A study of Mus musculus with 2 samples.

How the data were processed

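The data are 2 libraries of 3′ single-cell RNA sequencing made on the 10x Genomics platform, 1 from normal pancreas and 1 from pancreatic tumours of mice, each deposited as a matrix of genes by cell barcodes. Per the submitters' processing notes and the file headers, the matrices were made with Cell Ranger 3.1.0 on the mm10 genome build. The deposited values are raw UMI counts per gene and barcode, not normalized, for 27998 genes. The deposited barcode lists had already been called as cells. No cell annotation was used, and neither GFP nor Cre is among the genes listed. The labels' protocols state that normal tissue was digested with pronase, collagenase P and DNase and sorted for GFP, and tumours with collagenase IV, dispase, DNase and then trypsin and sorted for GFP and PDPN, so that digestion, gate and group cannot be separated.

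Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes, which left 4616 normal and 2573 tumour cells. Doublets were scored in each library with Scrublet. Its automatic threshold marked 2.08% of the normal cells, and 96 were removed. It marked 0.117% of the tumour cells, under a limit of 0.5% set in advance, so the 53 cells with the top scores (2.06%) were removed at the expected rate of 0.8% per 1000 cells. Both libraries were clustered together without integration (scanpy 1.11.5, igraph 0.11.9): counts scaled to 10000 per cell, log transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at a resolution of 0.5. A cluster took the name of the class whose fixed markers were detected in most of its cells, if at least 3 of them were found in at least 25% of cells. It stayed unnamed if its top 10 genes by fold held more markers of another class than of its own, or if its median UMI count was under 1 in 3 of its library's median with none of its markers in the top 10. In this rule the markers of myCAF-like, iCAF-like and universal fibroblasts counted as fibroblast markers. That choice was made after the clusters were seen, since otherwise the Schwann marker Ncam1 would have left the cluster led by Cthrc1 unnamed, and results without that cluster were computed too. Tumour fibroblast-like clusters of at least 20 cells were named as a subtype if the median log2 fold of its measured markers over the other tumour fibroblast-like cells was at least 1 and the highest of the subtypes, and at least 3 markers were 2-fold higher, a rule also written after the clusters were seen.

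Raw counts were summed over the fibroblast-like cells of each library and given as CPM, counts scaled to a sum of 1000000. A fold is tumour CPM over normal CPM, with the exact 95% interval of a ratio of 2 Poisson counts (scipy 1.17.1). A gene was called at least 2-fold apart if its interval also excluded 1 and it had at least 50 CPM in either sum. A count of 0 was set to a floor of 3 counts, which is 0.210 CPM in the normal and 0.107 CPM in the tumour sum, and the fold given as a bound. For 28 gene lists fixed in advance, members with at least 20 CPM in either sum entered a median log2 fold, whose percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. It describes these libraries and tests nothing. Of the 620 genes on the lists, 618 were found. Intervals of CPM, folds and shares cover counting error only, not differences between mice. A count of 1 UMI is 0.0701 CPM in the normal and 0.0358 CPM in the tumour sum. To compare shares of cells across depths, each cell was thinned without replacement to 5000 UMIs, the 10th percentile of the normal fibroblast-like cells rounded down to a multiple of 100.

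Genes were named by a rule set before the data were examined: Fabp4 and Pdpn; the 12 genes with the highest and the 12 with the lowest fold among genes called 2-fold apart with a UMI in at least 10% of the class's cells in the higher library, leaving out mitochondrial, ribosomal protein, sex-linked and unnamed genes and the markers of classes other than fibroblast-like, stellate, pericyte-like and mesothelial-like; the 2 highest and 2 lowest measured members of each list; and class markers where a class is described. The rule as written also leaves subtype markers such as Tnc and Acta2 out of the 12. A first run had kept them, and the rule was applied as written after those values were seen, so that they are named through their lists only. Some genes that the rule selects are left out of the text and the gene figure. Il6 was named as a subtype marker. Cthrc1, G0s2 and Inmt only identify clusters. Gene positions came from the GENCODE vM21 annotation of GRCm38, the assembly behind mm10, matched by Ensembl identifier.

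The calculation was checked on simulated sums drawn from the normal fibroblast-like means at the real totals with 200 changed genes. Of 3365 genes in that step, all 49 genes raised 2.5-fold, all 50 raised 4-fold and all 45 lowered to 0.4 of their level were called in the right direction. No gene raised 1.5-fold and none of the 3172 unchanged genes was called, and the interval held 1 for 94.9% of the unchanged genes. The simulated sums held counting error only, so they say nothing of variation between cells or mice. Alternatives covered the cell filter, doublets, clustering resolution and clustering each library alone, scaling (TMM and the median ratio of genes), equal weight per cell, the minimum CPM, thinning, restriction to cells with a Pdpn UMI, other definitions of the class, and the cycling rule. Statistics used numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and plots matplotlib 3.10.9.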

Results

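Single-cell RNA sequencing was used to profile GFP-positive cells from mice that carry the Rosa26-mTmG reporter and a Cre recombinase driven by the Fabp4 promoter. In such mice any cell with a history of Cre activity switches from a red to a green fluorescent membrane protein, so GFP marks cells by lineage. There were 2 libraries, 1 per group, and no replicates. The normal library held GFP-positive cells of pancreata from mice of 6 to 9 weeks of age, labelled as pancreatic stellate cells, the vitamin A storing mesenchymal cells of the organ. The tumour library held cells positive for GFP and for podoplanin (PDPN), a surface protein of fibroblasts, from tumours grown for 21 days after FC1245 pancreatic cancer cells were placed in the pancreas of 8-week-old mice, labelled as cancer-associated fibroblasts (CAFs). The normal library had 5437 barcodes with 36675424 unique molecular identifiers (UMIs), and the tumour library had 2942 barcodes with 33285044 UMIs. After filtering and removal of doublets, 4520 normal and 2520 tumour cells remained, with medians of 7066 and 10131 UMIs per cell. With 1 library per group no test of the conditions was possible. Intervals of CPM, folds and shares below are 95% intervals of counting error alone. Those of list medians and of their differences cover the spread between list members.

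The first comparison asked which cells each sort contained. Fibroblast-like cells, defined by Col1a1, Col1a2, Col3a1, Dcn, Lum, Pdgfra and similar genes, made up 32.8% (31.5 to 34.2%, Clopper-Pearson) of the normal cells, or 1484 of 4520. In the tumour library they made up 87.2% (85.8 to 88.5%), or 2197 of 2520. The normal library held nearly as many macrophage-like or monocyte-like cells, at 31.0% (29.6 to 32.3%), and endothelial-like cells, at 29.8% (28.5 to 31.2%). The tumour library had 2.06% (1.54 to 2.70%) and 0.238% (0.0874 to 0.518%) of these classes. Pericyte-like or smooth muscle-like cells were 3.32% of the normal and 0.0794% of the tumour cells. Lymphatic endothelial-like cells, a PDPN-positive type, were 0.288% (0.153 to 0.491%) of the normal and 2.70% (2.10 to 3.41%) of the tumour cells. Only the tumour sort was gated on PDPN, and tissue digestion also differed, so these shares describe the 2 sorts and not the 2 tissues. A cluster of 31 normal and 104 tumour cells stayed unnamed, because keratin genes and cycling genes led it, and was left out of the fibroblast-like class. It held 0.686% of the normal and 4.13% of the tumour cells.

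**Figure D1:**
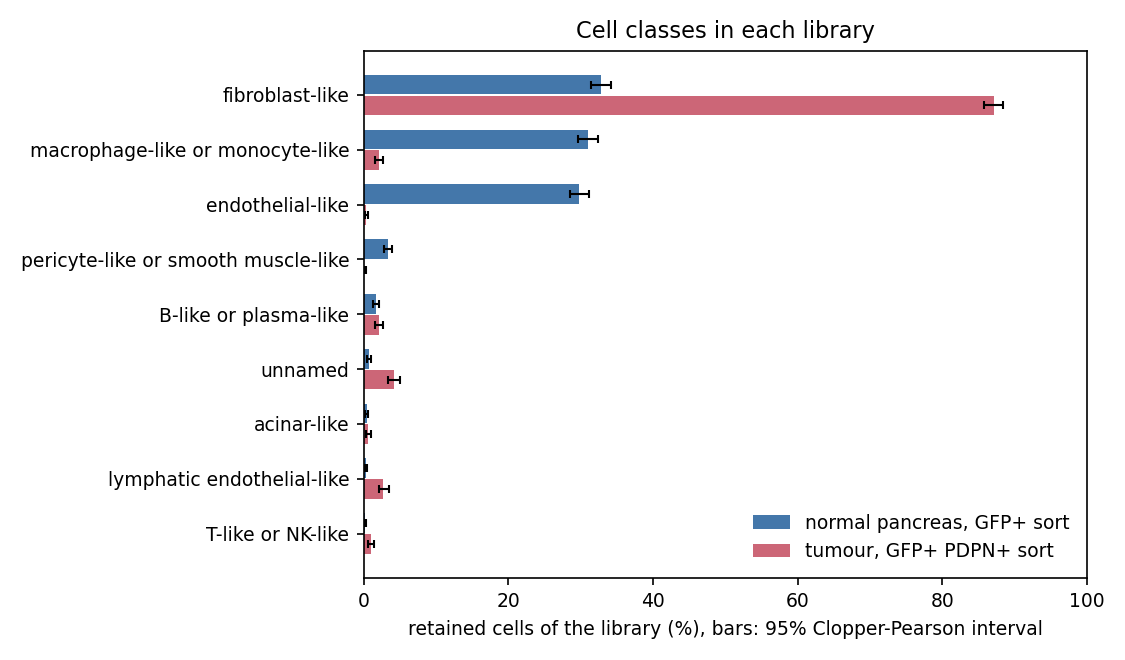
Share of retained cells (x axis, percent) in each cell class (y axis) for the normal and the tumour library, with bars for the 95% Clopper-Pearson interval. Fibroblast-like cells were 32.8% of the normal and 87.2% of the tumour cells, under different sorting gates.

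Fabp4, a fatty acid binding protein whose promoter drives the Cre, and Pdpn, the gate of the tumour sort, were examined in each class. Fabp4 (ENSMUSG00000062515, GRCm38 chromosome 3, 10204088 to 10208576) reached 10206 CPM (UMIs of the gene scaled to a class total of 1000000 UMIs, 10123 to 10289) in the normal endothelial-like cells, against 173.8 CPM (167 to 181) in the normal and 63.6 CPM (60.7 to 66.7) in the tumour fibroblast-like cells. That gap between fibroblast-like sums rested on few cells. After thinning each cell to 5000 UMIs, 10.3% of the normal and 10.7% of the tumour fibroblast-like cells had a Fabp4 UMI, and with clusters cut at a resolution of 1 the log2 fold was 0.15. In macrophage-like cells the thinned share with a Fabp4 UMI was 14.8% in the normal and 4.88% in the tumour library. Fabp4 was at 285 CPM in normal B-like and 371 CPM in normal acinar-like cells, so in that library other cells held a level like that of the fibroblast-like sum. In the tumour library B-like, T-like or NK-like and acinar-like cells had 0 Fabp4 UMIs, with upper limits of 21.6, 32.1 and 10.6 CPM. Tumour macrophage-like cells were at 5.81 CPM and lymphatic endothelial-like cells at 298 CPM. Median depths were 9033.5 UMIs in normal fibroblast-like, 10382 in tumour fibroblast-like, 8181.5 in normal macrophage-like and 8042 in tumour macrophage-like cells. Pdpn (ENSMUSG00000028583, chromosome 4, 143267431 to 143299564) was at 150.9 CPM (145 to 157) in the normal and 426.6 CPM (419 to 434) in the tumour fibroblast-like cells, 2.83-fold higher (2.70 to 2.96). After thinning, 47.5% of the normal and 74.7% of the tumour fibroblast-like cells had a Pdpn UMI, and unthinned the shares were 62.1% and 82.0%. In normal endothelial-like cells, with a median of 3955 UMIs, the unthinned share was 0.223%. Thinning left out 140 normal and 363 tumour fibroblast-like cells with fewer UMIs.

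The main comparison set tumour against normal fibroblast-like cells, the CAFs of this lineage against the fibroblasts of healthy pancreas. Summed over the class, the tumour library had 27942591 UMIs and the normal library 14271400. Among gene lists, cytokines and chemokines and the list of TGF-beta and YAP pathway genes and targets had the highest median folds. Genes of resting adventitial fibroblasts and of the basement membrane had the lowest. Of 3632 genes with at least 50 CPM in either sum, 340 were at least 2-fold higher in the tumour sum and 390 at least 2-fold lower. The median gene lay at a log2 fold of -0.25, over 6813 genes with at least 20 CPM. Scaling moved the split, to 597 higher and 207 lower under TMM and to 514 and 239 under the median ratio of genes. The normal cells of the class lay mostly in the clusters led by G0s2 (920 cells), Sema3c (270) and Inmt (264), and the tumour cells in those led by Cthrc1 (612), Apod (1243) and Thbs4 (312), so that cluster and library largely coincided. Tumour cells of the Cthrc1 cluster had a median of 21265 UMIs, against 7579 in the Apod and 12865 in the Thbs4 cluster. They therefore weighed more in the tumour sum than their number. With every cell weighted the same, 326 genes were higher and 369 lower.

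Among the genes with the highest folds, Thbs4, a thrombospondin of the extracellular matrix (ENSMUSG00000021702, chromosome 13, 92751590 to 92794818), had 1 UMI in the normal and 10275 in the tumour sum, a fold of 5248 (942 to 207299). A2m, a broad protease inhibitor (ENSMUSG00000030111, chromosome 6, 121635376 to 121679227), had 0 normal and 2109 tumour UMIs, at least 359-fold higher against a floor of 3 UMIs. Chl1, a neural adhesion protein, was 119-fold higher (73.0 to 208), and Wisp2, a CCN family matricellular protein, 75.5-fold (45.7 to 135). Ltbp2, a latent TGF-beta binding protein, was 57.2-fold higher (36.5 to 95.2; the Ltbp2 log2 fold was 5.84, and 4.72 with strict filters and 6.96 with doublets kept) and Inhba, which encodes the activin A subunit, 49.7-fold (36.4 to 69.7). Ddah1, Timp1, Chst11, Rgs16 and Cpxm2 were between 29.5-fold and 40.1-fold higher. Timp1, an inhibitor of matrix metalloproteinases, was the most abundant of these genes in the tumour sum, at 1543 CPM against 43.2 CPM. In the 52 tumour B-like cells, Thbs4, A2m and Chl1 had 0 CPM and Timp1 11.7 CPM.

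Among the genes with the lowest folds, Tenm4, a teneurin (ENSMUSG00000048078, chromosome 7, 96171246 to 96911093), was at 53.6 CPM in the normal and 0.966 CPM in the tumour sum, 55.5-fold lower (37.8 to 84.7). The Tenm4 log2 fold was -4.67 with lenient filters instead of -5.79. Efhd1, a calcium-binding protein of mitochondria (ENSMUSG00000026255, chromosome 1, 87264363 to 87310839), was 47.0-fold lower (35.4 to 63.7). Dlk1, an inhibitor of adipocyte differentiation, Pcsk6, a proprotein convertase, and Ces1d, a carboxylesterase, were 13.2-fold, 13.1-fold and 13.1-fold lower. Abca8b and Abca6, both ABC transporters, were 11.3-fold and 8.50-fold lower. Hpgd, which inactivates prostaglandins, was 9.29-fold lower (8.12 to 10.7), and Arhgap20, Limch1, Fam150b and Cbfa2t3 between 8.42-fold and 11.0-fold lower. Markers of other cell types also differed between the sums. Acinar markers totalled 961 CPM in the normal and 127 CPM in the tumour sum, and adipocyte markers 643 and 38.0 CPM. Endothelial markers totalled 534 and 216 CPM, macrophage markers 152 and 22.7 CPM, and B or plasma cell markers 134 and 1.22 CPM. Among totals higher in the tumour sum, the largest rested mostly on single genes. Spp1 made up 1031 of 1141 CPM of ductal or tumour epithelial markers (75.8 CPM in the normal sum). Ncam1 made up 158.9 of 169 CPM of Schwann or neural markers (20.04 CPM), and Pdpn 426.6 of 431 CPM of lymphatic endothelial markers (157 CPM). Neutrophil, mast, T or NK, endocrine and erythroid totals were also higher in the tumour sum, at 4.55 CPM or less.

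**Figure D2:**
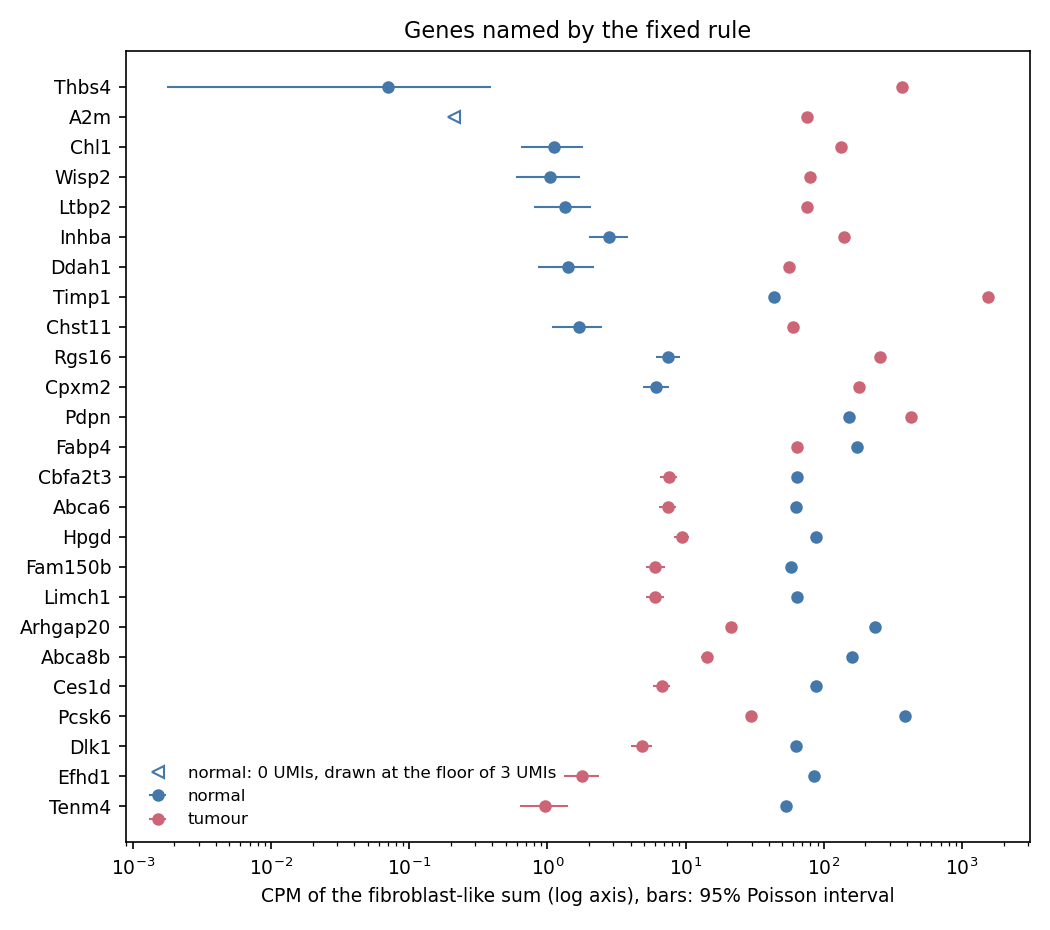
CPM of the fibroblast-like sum (x axis, log scale) in the normal and the tumour library for Fabp4, Pdpn and genes with the highest and the lowest fold (y axis), with 95% Poisson intervals. Thbs4 had 1 normal UMI, and A2m had 0, drawn at the floor of 3 UMIs (0.210 CPM).

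Matrix genes differed by kind. Of 15 measured fibrillar and associated collagens, 7 were at least 2-fold higher and 2 lower in the tumour sum, with a median log2 fold of 0.68, at the 99.6th percentile of 10000 random lists matched on expression. Without the Cthrc1 cluster that median was 0.21, at the 86.0th percentile. Col11a1 was 60.4-fold higher (29.2 to 151) and Col12a1 13.8-fold (12.4 to 15.3), while Col5a3 was 4.64-fold lower (4.49 to 4.79) and Col14a1 2.15-fold lower (2.10 to 2.20). With strict filters the Col14a1 log2 fold was -0.87 instead of -1.10, less than 2-fold. None of 16 measured basement membrane genes was at least 2-fold higher and 11 were lower, with a median log2 fold of -1.36 below all random lists. Endothelial markers were also lower in the tumour sum. Col4a4 was 7.62-fold lower (6.52 to 8.93) and Col4a3 6.25-fold lower, while Col4a5 and Agrn were at 1.06 and 1.15 times the normal level, with intervals that include 1. Matricellular proteins and glycoproteins had 9 of 24 members higher and 4 lower, with a median of 0.67. Tnc, tenascin C, was at 7.64 CPM in the normal and 710.8 CPM in the tumour sum, 93.1-fold higher (77.1 to 113). Spp1, osteopontin, had 1 normal and 28803 tumour UMIs, a fold of 14711 (2640 to 581067), and was at 17.6 CPM in tumour B-like and 3991 CPM in tumour macrophage-like cells against 1031 CPM in the fibroblast-like sum. Smoc2 was 5.07-fold lower, and Efemp1 was at 811 CPM in the normal and 262 CPM in the tumour sum. Proteoglycans were split, with 5 of 17 higher and 7 lower. Sdc1 was 17.4-fold and Prg4 17.1-fold higher (the Prg4 log2 fold was 5.09 with strict filters instead of 4.09, and Prg4 was at 470.3 CPM in normal and 374 CPM in tumour macrophage-like cells), and Ogn was 4.50-fold and Sdc2 2.95-fold lower. Of 18 genes of collagen processing, 3 were higher and 1 lower, with Lox, a collagen crosslinking enzyme, 4.01-fold higher and P4ha3, with 2 normal UMIs, 178-fold higher (49.2 to 1475). Pcolce2 was 5.53-fold lower and Loxl2 1.36-fold lower. Their list median was 0.54, and 0.10 without the Cthrc1 cluster. Of 22 proteases and inhibitors, 6 were higher and 4 lower. Mmp13, with 0 normal UMIs, was at least 113-fold higher but had a UMI in only 1.18% of the tumour cells and was at 60.0 CPM in tumour macrophage-like cells against 23.7 CPM, Adamts5 4.69-fold lower and Fap 2.42-fold lower.

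The contractile and signalling lists had positive medians. In the contractile cytoskeleton list, 7 of 18 members were at least 2-fold higher and 0 lower, with a median log2 fold of 0.84. Without the Cthrc1 cluster 3 were higher and 1 lower, with a median of 0.44. Tagln was 54.9-fold higher (48.5 to 62.5) and Acta2, smooth muscle actin, 47.9-fold (40.5 to 57.1), while Myh10 and Zyx were 1.44-fold and 1.33-fold lower. The Acta2 gap depended on the class, since with pericyte-like or smooth muscle-like cells added its log2 fold was -0.01. Of 21 measured members of the TGF-beta and YAP list, 12 were higher and 2 lower, with a median of 2.07, led by Wisp2 and Ltbp2. That list holds TGF-beta ligands, receptors and latent binding proteins beside targets, so its median does not measure targets alone. Amotl2 and Ltbp1 were 2.70-fold and 2.48-fold lower. Cytokines and chemokines had the highest median of all lists, 2.44, with 14 of 21 members higher and 1 lower. Cxcl5 was 90.2-fold higher (38.5 to 278), Lif 34.2-fold (27.0 to 44.0) and Il6 26.8-fold (24.8 to 29.0), whereas Ccl11, eotaxin, was 3.31-fold lower and Il34 1.76-fold lower. With strict filters the Il34 log2 fold was -1.60 instead of -0.81. Growth factors had 15 of 23 members higher and 3 lower, with a median of 1.31. Ereg and Nrg1, ligands of the EGF receptor family with 2 and 3 normal UMIs, were 191-fold (52.7 to 1580) and 99.8-fold (34.0 to 485) higher, and Igfbp6 and Fgf10 were 3.20-fold and 3.11-fold lower. Tumour macrophage-like cells had Ereg at 110 CPM and Nrg1 at 91.0 CPM, against 26.8 and 21.0 CPM in the tumour fibroblast-like sum. In complement and acute phase, 8 of 14 were higher and 2 lower, with a median of 1.24. Saa3 was 44.5-fold and Ptx3 7.73-fold higher. Saa3 was at 652 CPM in normal and 1026 CPM in tumour macrophage-like cells, and over all retained cells the Saa3 log2 fold was -0.50. Cfd was 29.4-fold lower, but only 0.744% of thinned normal cells had a UMI of it, and the Cfd log2 fold, -4.88, was -1.95 with strict filters and 5.28 against normal cells of female mice. Among Wnt, BMP and hedgehog genes, 8 of 17 were higher, with Wnt4 17.5-fold and Wnt2 11.6-fold, and 4 lower, with Bmp4 and Rspo3 both 4.51-fold. Their median was 0.94, and it was -0.11 without the Cthrc1 cluster.

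Quiescent and universal fibroblast genes, which mark resting adventitial fibroblasts, had the lowest median of all lists, -1.51, below all random lists. Of 23 measured members 14 were at least 2-fold lower and 1 higher. Efhd1 and Sema3c were lowest, Sema3c at 276.7 CPM in the normal and 17.6 CPM in the tumour sum, 15.7-fold lower (14.3 to 17.3). Cxcl14 was 2.17-fold higher and Gpx3 1.19-fold higher. With strict filters the Cxcl14 log2 fold was 0.53 instead of 1.11, below 2-fold. Retinoid genes had 3 of 10 members higher and 0 lower, with a median of 0.80. Stra6, the retinol importer, with 7 normal UMIs, was 82.6-fold higher (40.0 to 206), and Rarres2 and Aldh1a1 were 1.78-fold and 1.51-fold lower. Among 9 measured lipid genes, Angptl4 and Apod were 4.56-fold and 2.93-fold higher, and Fabp4 and Lpl 2.73-fold and 2.01-fold lower, with a median of -0.11. The Fabp4 log2 fold, -1.45, was -0.54 with lenient and -0.90 with strict filters, 0.15 at a resolution of 1 and 0.52 against normal cells of female mice, and the Lpl log2 fold, -1.01, was -0.97 with doublets kept. The Angptl4 log2 fold, 2.19, ranged from 1.48 without the Cthrc1 cluster to 3.56 at a resolution of 1.

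The stress and hypoxia lists also had positive medians. Of 26 dissociation and immediate early genes, 14 were at least 2-fold higher and 0 lower, with a median log2 fold of 1.30. Fosl1 was 39.1-fold and Ier3 26.2-fold higher, and Atf3 and Klf2 were 1.96-fold and 1.93-fold lower. Klf2 was at least 2-fold lower with strict filters, with doublets kept and at a resolution of 1. In cells with a Pdpn UMI both Klf2 and Atf3 were. Heat shock genes had 8 of 14 members higher, with a median of 1.04, among them Hspb1 at 5.92-fold and Dnajb1 at 4.57-fold, with Dnaja1 1.28-fold lower and Hsp90ab1 1.17-fold higher. Of 20 glycolysis and hypoxia genes, 11 were higher and 1 lower, with a median of 1.11. Slc16a3, a lactate exporter, was 36.6-fold and Egln3 18.0-fold higher, and Adm and Hk1 were 2.25-fold and 1.76-fold lower. Tumour macrophage-like cells had Slc16a3 at 344 CPM and Egln3 at 170 CPM, against 35.9 and 24.0 CPM in the tumour fibroblast-like sum. The Adm log2 fold, -1.17, was -0.83 with strict filters and 0.01 over all retained cells. Without the Cthrc1 cluster the glycolysis and hypoxia median was 0.10. In oxidative stress and metallothioneins, 5 of 14 were higher and 1 lower, with Mt2 7.14-fold and Hmox1 6.68-fold higher, Gstm1 6.79-fold lower and Gclm 1.42-fold lower. Hmox1 was at 873 CPM in tumour macrophage-like cells, against 105 CPM in the tumour fibroblast-like sum.

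The remaining lists had medians between -0.62 and 0.15. None of 22 nuclear genes of oxidative phosphorylation was 2-fold apart, with a median log2 fold of 0.05 and Cycs, Cox5a, Sdha and Ndufa1 at 1.59, 1.47, 0.747 and 0.926 times the normal level. Antigen presentation genes also had no member of 8 that was 2-fold apart, with H2-K1, B2m, Tap2 and Psmb9 at 1.38, 1.11, 0.572 and 0.522 times the normal level. Interferon response genes had a median of -0.62, at the 1.67th percentile, with 2 of 17 lower, Ifit2 at 4.29-fold and Ifit3 at 2.02-fold (Ifit3 log2 fold -0.96 with strict filters), and Irf1 and Isg15 at 1.90 and 1.69 times the normal level. For the unfolded protein response the median was 0.15, with Manf 2.10-fold (Manf log2 fold 0.96 with strict filters) and Creld2 1.87-fold higher, and Atf3 and Mia3 at 0.511 and 0.798 times the normal level. Cholesterol synthesis had a median of -0.27, with Cyp51 2.61-fold higher and Sc5d 3.20-fold lower. Cyp51 was no longer 2-fold apart with equal weight per cell, nor was Sc5d over all retained cells. Axon guidance genes had a median of -0.44, with Ncam1 52.7-fold and Sema5a 1.56-fold higher and Sema3c and Robo2 15.7-fold and 6.07-fold lower. Mesenchymal transcription factors had a median of -0.24, with Runx1 28.0-fold and Runx2 4.58-fold higher and Ebf2 and Ebf1 3.58-fold and 2.82-fold lower. For receptors and surface proteins the median was 0.06. Lrrc15, a surface protein of myofibroblast-like CAFs with 0 normal UMIs, was at least 272-fold higher, Icam1 5.40-fold higher, and Lifr and Itga11 3.46-fold and 2.74-fold lower. Too few genes of the cycling list reached 20 CPM for a median.

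**Figure D3:**
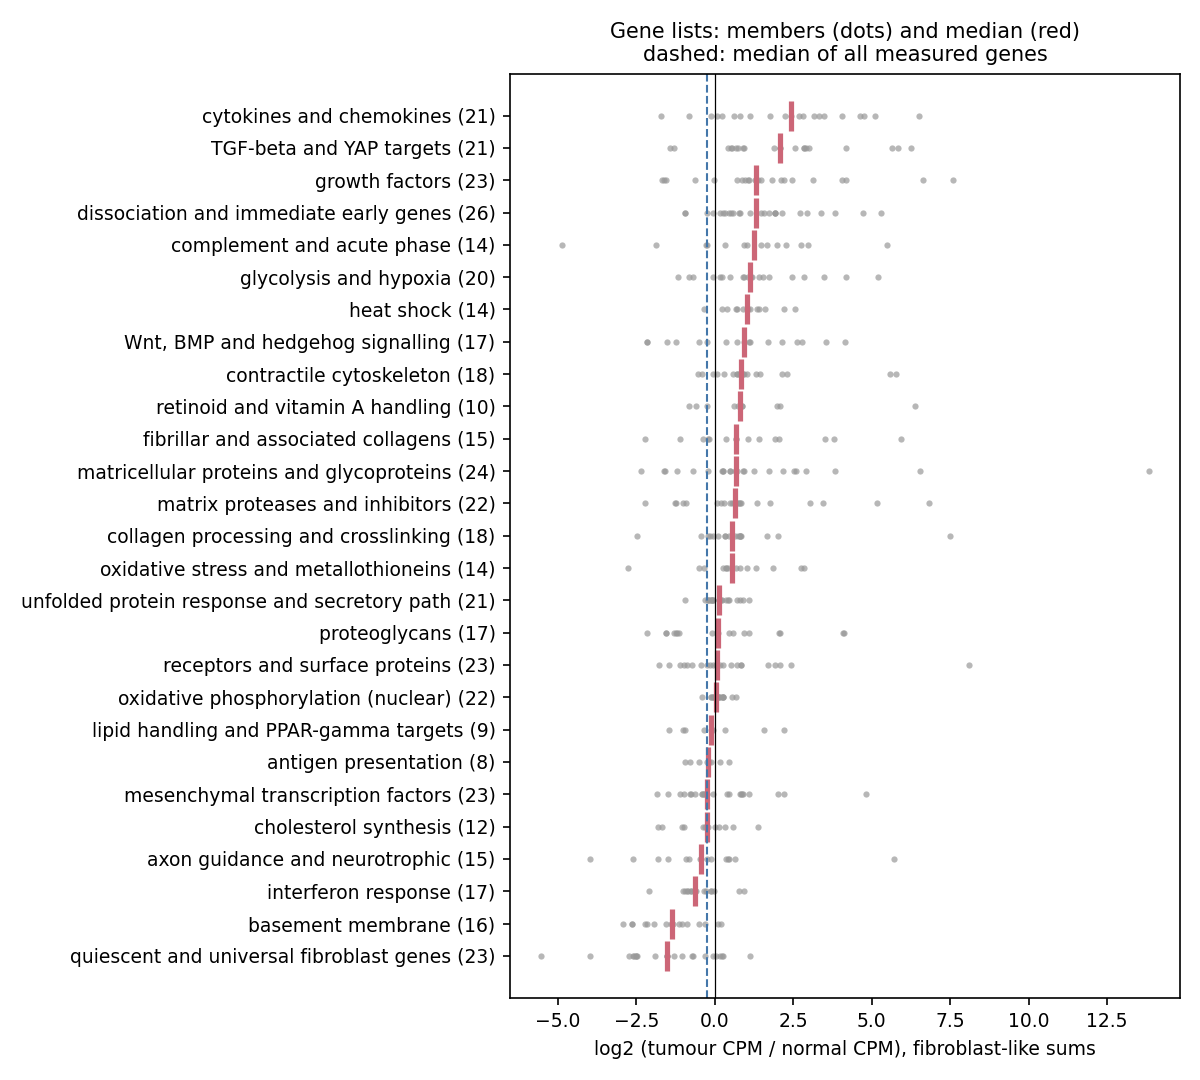
log2 of tumour over normal CPM in the fibroblast-like sums (x axis) for the measured members of each gene list (dots; number in brackets on the y axis), with the list median in red and the median of all measured genes, -0.25, dashed. Cytokines and chemokines had the highest median, 2.44, and quiescent and universal fibroblast genes the lowest, -1.51.

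Subtypes of fibroblasts within the tumour library were then named from fixed markers. A cluster of 612 cells, 27.9% (26.0 to 29.8%, Clopper-Pearson) of the 2197 tumour fibroblast-like cells, was myofibroblast CAF-like (myCAF-like). In it 9 of 15 measured myCAF markers were at least 2-fold above the other tumour fibroblast-like cells, with a median log2 fold of 1.74. It also met the limits for antigen-presenting CAFs, on the only 3 such markers measured, all at least 2-fold higher with a median of 1.24, and took the name with the higher median. Acta2 was at 852 CPM there, at 33.6 CPM in the Apod cluster of 1243 cells and at 241 CPM in the Thbs4 cluster of 312 cells. Other myCAF markers were not confined to it. Tagln was at 1363, 83.7 and 1717 CPM in the Cthrc1, Apod and Thbs4 clusters, and Tnc at 1163, 36.8 and 870 CPM. The Apod and Thbs4 clusters met no subtype, and 0 of 2197 cells were in a cluster named inflammatory CAF-like (iCAF-like). Il6, an iCAF marker, was at 993, 1503 and 1649 CPM in the Cthrc1, Apod and Thbs4 clusters, against 47.2 CPM in the normal fibroblast-like sum. At a resolution of 1, 13.1% of the tumour cells that were fibroblast-like in that setting were iCAF-like and 19.97% myCAF-like. That class held 75.7% of the tumour library instead of 87.2%. Unnamed clusters whose most detected markers were of fibroblasts held 388 tumour cells. Clusters of at least 20 cells in that class had at most 306 CPM of Thbs4, against 1812 CPM in the Thbs4 cluster. These shares therefore cover different cells from the 27.9%. With the tumour library clustered alone the iCAF-like and myCAF-like shares were 13.9% and 16.3%, and at a resolution of 0.3 they were 68.1% and 29.1%.

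Cells with at least 2 genes of the S or G2/M phases were counted after thinning to 5000 UMIs. They were 6.92% (5.62 to 8.41%, Clopper-Pearson) of 1344 normal and 10.5% (9.10 to 11.96%) of 1834 tumour fibroblast-like cells. Without thinning the shares were 20.01% and 29.6%. The unnamed cluster, led by keratin and cycling genes, was left out of these shares. With it clustered again and its fibroblast-like parts added, the thinned shares were 7.26% and 11.9%. Normal macrophage-like and endothelial-like cells had thinned shares of 14.9% and 31.0%, above both fibroblast-like shares. Only 403 of 1347 endothelial-like cells reached that depth. Unthinned, the shares of these classes were 28.4% and 24.1%, between the fibroblast-like ones. Whether any of these shares reflect cycling was not tested.

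Sex-linked genes served as a check of which mice were pooled. Normal fibroblast-like cells had 2232 UMIs of 4 Y-linked genes (Ddx3y, Eif2s3y, Uty and Kdm5d), or 156 CPM, and 5426 UMIs of Xist, the RNA that silences an X chromosome in female cells. Y-linked UMIs without Xist were found in 771 of these cells, and Xist without Y-linked UMIs in 484. Tumour fibroblast-like cells had 1 Y-linked UMI and 21289 Xist UMIs. The normal library therefore pooled cells of male and female mice and the tumour library held cells of female mice, and against the 484 normal cells with Xist alone 347 genes were at least 2-fold higher and 414 lower.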

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

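The tests in this part and their criteria were written after the patterns had been found and before the test values were seen, but restricting them to the list members of each pattern was chosen after first values were seen, which moved 2 values, and 2 tests were judged unable to decide after their values were seen. Y-linked genes, which no comparison between the groups used, were at 156 CPM in normal fibroblast-like cells and at 0.0358 CPM in tumour ones. Several list medians had the opposite sign in another cell class, but most of their intervals over members include 0. The immediate early list was at a median log2 fold of -0.26 (-0.59 to 0.70) in B-like and -0.71 (-1.43 to 0.64) in macrophage-like cells. In lymphatic endothelial-like cells it was at -0.15 (-1.01 to 0.56), against 1.30 in fibroblast-like cells. The lymphatic comparison rested on 13 normal cells with 57987 UMIs. Over shared members the median difference from fibroblast-like cells was -1.17 (-1.48 to -0.78), -1.86 (-2.29 to -1.43) and -1.17 (-1.54 to -0.55). These intervals cover the spread between list members, not differences between mice. For the lists that follow the difference was not tested. The heat shock list was at -0.80 in macrophage-like cells against 1.04. The cytokine list was at -2.11 in B-like cells (3 measured members) and at -0.21 in lymphatic endothelial-like cells (4 members), against 2.44, and the oxidative stress list at -0.01 in B-like cells (value -0.00804) against 0.54. Other medians had the same sign as in fibroblast-like cells, among them heat shock in lymphatic endothelial-like cells, at 1.39, and cytokines in macrophage-like cells, at 1.02. Normal and tumour macrophage-like cells lay mostly in different clusters, and in the cluster that held 328 normal and 49 tumour cells the immediate early median was -0.21 and the cytokine median 2.03.

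The first pattern was the higher level of immediate early and cytokine genes in tumour fibroblast-like cells, which were digested differently. A digestion effect on all cell types alike would have raised the immediate early list in B-like, macrophage-like and lymphatic endothelial-like cells too, but the median of its 3 medians there, over the members measured in fibroblast-like cells, was -0.23. A difference in depth was not tested by thinning (median 1.47), since CPM does not depend on depth. Nor was dissociation of fibroblasts alone decided in cells with at most 1.04% immediate early UMIs: the cytokine median there was 0.90 instead of 2.44, with Il6 263-fold (142 to 552), Lif 41.9-fold (26.8 to 68.6), Cxcl1 6.88-fold and Ccl2 1.24-fold (1.05 to 1.45) higher, but the immediate early list stayed at 1.17 and 41 of the 70 tumour cells were of the Cthrc1 cluster. Dissociation of fibroblasts and activation in the tumour, the difference the design names, both stay open.

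The second pattern was the lower level of quiescent and universal fibroblast genes in the tumour library, which alone was gated on PDPN. Among cells with a Pdpn UMI in both libraries the list median was -1.55, and against normal cells of female mice it was -1.43. The latter argues against sex as the whole cause. The former argues against unequal Pdpn RNA as the whole cause, but does not decide on the gate, which was on the protein. In the normal library the Sema3c cluster had the largest thinned share with a Pdpn UMI, 58.5%, against 43.0% and 46.6% in the G0s2 and Inmt clusters. Without the normal cluster led by Sema3c, Dpp4 and Pi16 the median over the same members was -0.67 instead of -1.51. Only 1 tumour cell lay in that cluster, so its scarcity in the tumour library may account for part of the gap. That cluster is itself recognised by genes of the list, however. The median difference of the list members, 0.65, had an interval over members of -0.17 to 1.62. Scarcity was judged by cluster alone, in a clustering without integration. At a resolution of 1, a cluster of 250 tumour cells had 8 of 15 universal fibroblast markers raised. These were at least 2-fold above the other tumour fibroblast-like cells. Whether cells of the Sema3c cluster were lost, altered or not sorted was not tested.

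The third pattern was the number of genes at least 2-fold apart, 730, in libraries that pooled mice of different sex. Normal fibroblast-like cells of male and female mice, 771 and 484 cells, were at least 2-fold apart in 28 of 3489 genes, sex-linked genes left out. Sex of the mice is thus argued against as the main cause. In cells with a Pdpn UMI 348 genes were higher and 376 lower, but that UMI is RNA and the gate was on the protein. Age, digestion, gate and library stay open beside the tumour itself.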

How the results depend on the processing

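Alternatives fixed before the data were examined and 6 kinds added afterwards gave 70 values of the main results, of which 42 lay within the limits set for no change. The added ones left out the Cthrc1 cluster, used normal cells of female mice, re-clustered the unnamed cluster, clustered each library alone for folds, and for list medians thinned the cells and left out the normal Sema3c cluster. Where no cause is given below, the cause was not tested. The 340 higher genes became 597 under TMM, 514 under the median ratio, 652 with a minimum of 10 CPM and 1366 with none, and the 390 lower genes 207, 239, 1131 and 2747, the last 2 because more genes were compared. With all retained cells 645 genes were lower. In the other settings the counts lay between 322 and 438 higher and 322 and 414 lower. The fibroblast-like share of normal cells was 30.2% with lenient and 35.5% with strict filters. Its share of tumour cells was 72.5% with strict filters, 75.7% at a resolution of 1, 89.5% at 0.3, 89.6% with libraries clustered alone, 62.9% without the Cthrc1 cluster and 89.3% with the unnamed cluster re-clustered. The strict filter and a resolution of 1 left 17.8% and 15.4% of tumour cells, and 0% and 1.73% of normal cells, in unnamed clusters whose most detected markers were of fibroblasts. The myCAF-like share was 19.97% at a resolution of 1 and 16.3% with libraries clustered alone, and the iCAF-like share 68.1% at 0.3, 13.1% at 1 and 13.9% alone, so subtype shares depended on the clustering. Shares of fibroblast-like cells with S or G2/M genes were 34.5% in normal and 41.6% in tumour cells with at least 1 gene. They were 0.967% and 2.45% with at least 3, and 20.01% and 29.6% without thinning, higher in the tumour each time. Of 297 list medians, 1 changed sign past the limits: Wnt, BMP and hedgehog genes, at -0.11 without the Cthrc1 cluster. Smaller changes of sign are not in that count. Under TMM the lipid median went from -0.11 to 0.23 and that of antigen presentation from -0.22 to 0.12. Cholesterol synthesis went from -0.27 to 0.07 and mesenchymal transcription factors from -0.24 to 0.10. Without the Cthrc1 cluster proteoglycans went from 0.11 to -0.17. The signs of medians near 0 thus depended on the processing. Of 2028 values of named genes, 1171 lay within their counting intervals, 851 outside with the same sign, and 6 changed sign. Of 126 or 127 genes compared, folds moved by over 1.5 times in 7 with strict and 5 with lenient filters, 5 with doublets kept, 10 at a resolution of 1, 22 with equal weight per cell, 15 after thinning, 23 against normal cells of female mice, 45 without the Cthrc1 cluster and 95 over all retained cells. TMM multiplied every tumour CPM by 1.27, and the median ratio raised its log2 by 0.25. Neither scaling could therefore move a fold by 1.5 times. Genes no longer 2-fold apart were Fabp4, Col14a1, Cxcl14, Ifit3, Adm and Manf with strict filters, Fabp4 with lenient ones, Lpl with doublets kept, Adm, Col14a1, Fap, Ifit3, Lpl and Ltbp1 under TMM, and Ifit3, Lpl and Prg4 without the Cthrc1 cluster. Calls were also lost by 20 genes over all retained cells, 7 with equal weight per cell and 5 against normal cells of female mice. After thinning, at a resolution of 1 and under the median ratio 4 were lost each. In cells with a Pdpn UMI and with pericyte-like cells added 2 were lost each. Genes newly 2-fold apart were 7 over all retained cells and at most 4 elsewhere. The log2 fold of Fabp4 was 0.15 at a resolution of 1 and 0.52 against normal cells of female mice, that of Cfd 5.28 against the latter, that of Acta2 -0.01 (-0.00502) with pericyte-like cells added, and those of Saa3 and Adm -0.50 and 0.01 (0.00734) over all retained cells. Depth limits genes near the floor: for a gene at 0 normal UMIs the upper 95% limit is 0.258 CPM.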

Other observations

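Of the 52 tumour macrophage-like cells, 49 lay in a cluster with 328 normal cells. In it 23 of 24 measured glycolysis and hypoxia genes were at least 2-fold higher in the tumour library, with a median log2 fold of 2.20, among them Slc2a1 at 29.4-fold (20.6 to 43.0), Bnip3 at 36.7-fold (24.5 to 56.7) and Vegfa at 30.8-fold (23.6 to 40.9). Arg1, arginase 1, had 0 normal and 1958 tumour UMIs there, at least 3681-fold higher, and Spp1 was at 21.2 and 4201 CPM. Of 13 measured heat shock genes 5 were at least 2-fold lower and 0 higher, with a median of -0.93. Pdpn, the gate of the tumour sort, was at 1.83 CPM in the normal and 194 CPM in the tumour cells of that cluster. Arg1, Spp1, Slc2a1, Bnip3 and Vegfa were singled out after their values were seen. Spp1 was at 1031 CPM in the tumour fibroblast-like sum. Col1a1 was at 24.8 CPM in the 1400 normal and 27.1 CPM in the 52 tumour macrophage-like cells, and at 8149 CPM in the tumour fibroblast-like sum. In the same cluster 10 of 11 measured quiescent and universal fibroblast genes (median 2.02), 7 of 8 proteoglycans (2.33) and 7 of 8 complement and acute phase genes (4.53) were also at least 2-fold higher in the tumour cells. These lists hold 24, 18 and 20 genes, and members entered only with at least 20 CPM in either library. Genes low in the normal cells could thus enter only by being high in the tumour cells, so that limit partly set these counts.

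When the unnamed cluster was clustered again, 46 tumour cells formed a group with 1 normal cell that was ductal-like or tumour epithelial-like, led by Krt18, Krt8 and Krt19. At a median of 21233 UMIs, 42 of these 46 cells had neither an Xist nor a Y-linked UMI, against 107 of the 2197 tumour fibroblast-like cells. Xist was at 27.7 CPM in these 46 cells and at 762 CPM in the tumour fibroblast-like cells. Another 54 tumour cells of the unnamed cluster were fibroblast-like, with Xist at 711 CPM, and 32 of them lay in a group led by Top2a and Ube2c.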
